A study of Mus musculus with 24 samples.

How the data were processed

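Total RNA from the livers of C57BL/6 mice was sequenced in 24 libraries, 3 for each of 8 groups formed by sex, genotype (wild type, WT, or lacking Cyp2b9, Cyp2b10 and Cyp2b13, Cyp2b-null) and diet (normal chow, ND, or a diet with 60% fat, HFD, for 10 weeks). Per the labels' protocols, male RNA was extracted with the RNeasy Plus Universal kit and made into libraries with the TruSeq Total RNA kit, and female RNA with Trizol and the NEB Next Ultra RNA kit. Both kit and extraction therefore go with sex. The deposited values are raw counts of reads per gene symbol, 1 table per sex. Per the submitters' processing notes, the tools named are FastQC, Trimmomatic, GSNAP, Subread and edgeR and the build is GRCm38.p5; their order, settings and versions, and whether the counting used strand, are not given in the sources used here. Reads shared by close paralogues, such as the Cyp2a, Cyp2b and Cyp3a genes, can be split between them or dropped at that step, so their single values are uncertain.

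Groups were taken from the sample titles. In 6 female libraries the genotype characteristic contradicts the title; the titles were followed because they also give the diet. The labels do not say that the libraries of a group come from separate animals, so p-values measure the spread between these libraries. No pair of libraries within a group matched within sampling noise (lowest chi-square per degree of freedom 6.19). Pairs across groups were not compared in this way. Among the male counts 1806 symbols occurred more than once and their counts were summed. Both tables held 46093 symbols, of which 25 had been turned into dates by a spreadsheet. These took at most 0.160% of a library, stayed in the library totals and were not tested.

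Library totals ran from 8.28 M to 20.2 M counts in males and from 2.01 M to 2.66 M in females, so low transcripts were measured less precisely in females. Each sex was fitted alone with edgeR 4.0.16 (R 4.3.3), with 1 term per group over its 12 libraries, TMM scaling, a filter on low counts by group, robust dispersions and the quasi-likelihood test. Fitting the 4 groups together gives them 1 shared estimate of the spread. The filter left 14873 genes in males and 11830 in females. Contrasts were Cyp2b-null minus WT on each diet, HFD minus ND in each genotype, and their interaction. A joint fit of the 24 libraries (15043 genes) tested the female minus the male effect. P-values were adjusted by Benjamini-Hochberg over the genes tested, and an adjusted p below 0.05 was a call. The square root of the common dispersion was 0.340 in males and 0.269 in females. Without the divergent male library it was 0.219 and with the term for the female library sides 0.211. Levels are counts scaled to library size (CPM) with TMM factors; log2 levels used a prior count of 2. Intervals are 95% and rest on the spread in the fit. Where a group had 0 counts, a bound was set at 3 counts over the group, which covers counting error only.

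The groups, the designs, the alternatives listed in advance, the gene lists and the rule for the genes named were fixed before the data were examined. The rule named, in each comparison within a sex, the targeted genes, up to 6 called genes with the largest rise and 6 with the largest fall whose libraries did not overlap, with an average log2 CPM of at least 1 and no predicted or clone name, up to 3 called members of lists with at least 3 of them, and otherwise the member with the smallest p of each called list. For a sex difference it named up to 3 genes each way. The same rule served for the fits added after the data were seen, without the divergent male library and with the term for the female library sides. Other names, such as list members adjusted over the list alone, genes shared between comparisons, Hexim1, Nceh1 and Gm15343, were chosen after their values were seen.

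Of the 39 lists with 1016 entries in all, the 37 other than the targeted genes and the sex chromosome transcripts were tested where at least 4 members were measured, and the targeted genes were left out of each. Camera in limma 3.58.1, with a preset correlation of 0.01, compares a list with the other genes, and was repeated with an estimated correlation. Fry tests whether the genes of a list move one way on balance and, in its mixed form, whether they change in either direction; neither form compares the list with other genes. Alternatives were RLE scaling, no filter, DESeq2 1.42.0, the compared groups alone, the replicate number as a block, the first of duplicated symbols in place of their sum, and leaving out each library in turn. Replicate numbers come from the titles, and nothing there says that they mark a shared batch or litter. Same-numbered libraries deviated together from their group means, with r above 0.1 in every pair, between WT ND and WT HFD (0.11 to 0.127 in males, 0.139 to 0.564 in females), and not in every pair of the other comparisons within a sex. The numbers were therefore taken to pair the libraries in the diet comparisons in WT alone. That pairing is uncertain, since female WT ND 2 deviated further with WT HFD 3 (r 0.319) than with WT HFD 2 (0.139). The main fits do not use it. RLE scaling moved the median log2 difference by at most 0.04 in any comparison. Sequencing batch and time of day of sampling are not given in the sources used here. Transcript lengths, GC content and positions came from GENCODE M21 on GRCm38.

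The steps were tested on simulated data, with counts drawn from the real means and library sizes and changed genes of known size. For the male genotype comparison on ND (14794 genes) they recovered 9.09%, 70.1% and 95.5% of genes changed by log2 1, 2 and 3, with 3 false calls. With 11 libraries (14991 genes) the shares were 32.8%, 83.6% and 87.9%, with 18 false calls. For the female genotype comparison on ND (11780 genes) they were 16.7%, 72.7% and 92.3%, with 9 false calls, and for the sex difference of that comparison (14439 genes) 1.52%, 33.3% and 71.9%, with 3 false calls. Changes of log2 1 were thus mostly missed in these simulations at this depth and number of libraries. Genes were drawn independently from a common mean over the groups, with no divergent library and no female library sides. The shares recovered therefore need not hold in the real data.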

Results

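Liver RNA was sequenced from male and female C57BL/6 mice that were either wild type (WT) or labelled as lacking Cyp2b9, Cyp2b10 and Cyp2b13, the murine hepatic members of the Cyp2b family of cytochrome P450 monooxygenases that metabolise drugs and unsaturated fatty acids (Cyp2b-null). Mice of each sex and genotype received normal chow (ND) or a diet with 60% fat (HFD) for 10 weeks, which gave 8 groups of 3 libraries. The series asks what role Cyp2b enzymes play in diet-induced obesity and in the handling of hepatic lipids. Deposited counts per gene summed to between 8.28 M and 20.2 M in the 12 male libraries and to between 2.01 M and 2.66 M in the 12 female libraries. After low counts were removed, 14873 genes were tested in males and 11830 in females. RNA extraction and library kit differed between the sexes, so sex and kit cannot be told apart. Levels are given as counts scaled to library size (CPM), as mean ± SD (n = 3 libraries), and log2 differences as estimate ± SE.

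Xist, the transcript expressed from the inactive X chromosome, had 0 to 5 counts in the male libraries and 725 to 1794 in the female ones, and Y-linked genes had 1203 to 4579 counts in males and 0 to 2 in females, so every library carried the sex of its label. In 6 female libraries the genotype given as a sample characteristic contradicts the one in the title, and groups here follow the titles. Library 1 of the males labelled Cyp2b-null on ND stood apart from the other male libraries. Its median Spearman correlation with the other 11 male libraries was 0.8002, against 0.965 or more for each of the others, and mitochondrially encoded genes took 32.0% of its counts, against at most 7.76%. Among females, library 1 of the WT ND group had 13.96% mitochondrially encoded counts, against at most 8.54% in the others, and the first principal component (29.2% of the variance) parted 5 libraries from the other 7 without following genotype or diet. The side with 5 held WT ND 1, WT HFD 1, Cyp2b-null ND 2 and 3 and Cyp2b-null HFD 2. Counts of called genes are therefore given also without the divergent male library, and for females with a term for these sides; both were chosen after the data were seen. The female sides were defined from the counts they adjust, so the counts with that term only describe.

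**Figure D1:**
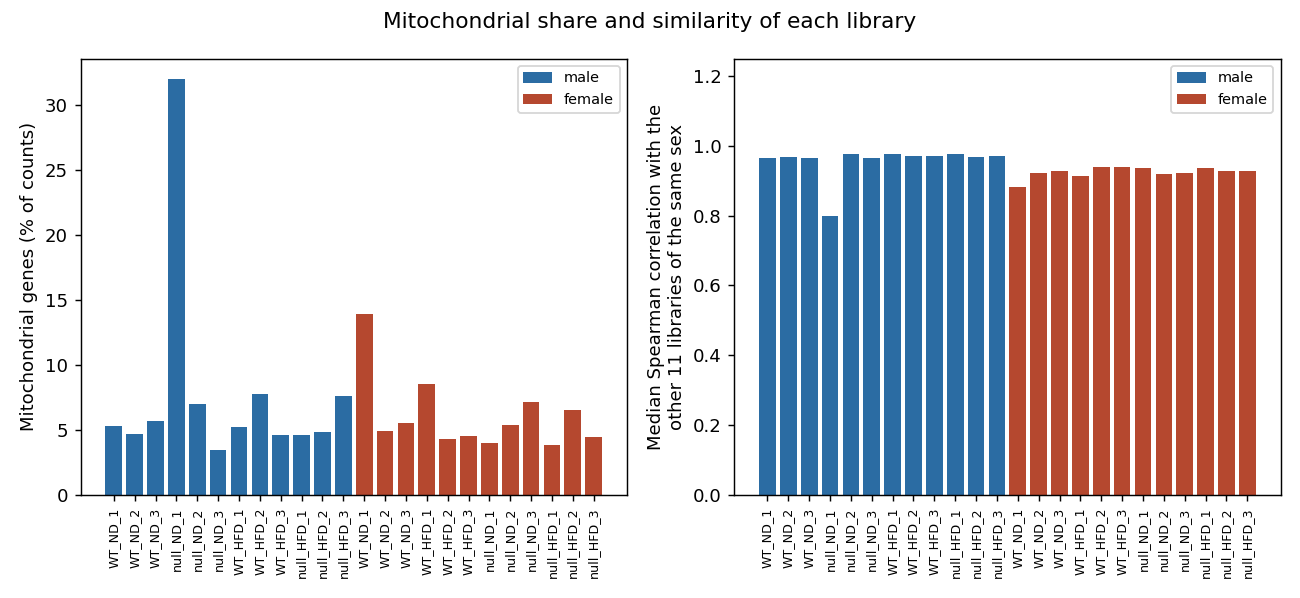
Bars give, for each of the 24 libraries (males blue, females red), the percentage of counts from mitochondrially encoded genes (left) and the median Spearman correlation with the other 11 libraries of the same sex (right). Library 1 of the males labelled Cyp2b-null on ND stands out at 32.0% and 0.8002.

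The targeted genes lie together on chromosome 7 (GRCm38, GENCODE M21, forward strand): Cyp2b10 at 25897620 to 25926624, Cyp2b13 at 26061497 to 26096197 and Cyp2b9 at 26173411 to 26210661, within 313 kb from the start of Cyp2b10 to the end of Cyp2b9. All are protein coding. In females the counts followed the titles. Cyp2b13 had 565 to 1138 counts in the 6 WT libraries and 0 in the 6 Cyp2b-null libraries, which puts it at least 982-fold lower on ND and at least 761-fold lower on HFD, with 3 counts over the group as the floor. Cyp2b9 had 788 to 1245 counts in WT and 0 to 17 in Cyp2b-null females, and its mean went from 450 ± 53.5 CPM in WT to 3.91 ± 2.58 CPM on ND and from 392 ± 109 to 0.811 ± 0.761 CPM on HFD. Cyp2b10 was low throughout, with 14 to 97 counts in WT and 0 to 17 in Cyp2b-null females, and its differences did not pass the test on ND (-3.02 ± 0.87, edgeR adjusted p = 0.424) or HFD (-4.87 ± 1.2, adjusted p = 1.0).

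Male livers gave another picture. Cyp2b13 was equally low in WT and in males labelled Cyp2b-null, at 2.72 ± 0.689 against 2.84 ± 1.92 CPM on ND (log2 difference 0.12, 95% interval -0.84 to 1.08) and 3.83 ± 0.0645 against 3.74 ± 0.531 CPM on HFD. Cyp2b9 on ND had 1, 2 and 4 counts in the WT libraries and 24, 29 and 59 in those labelled Cyp2b-null (3.67, 95% interval 1.49 to 5.84, adjusted p = 0.192). On HFD it stood at 22.5 ± 16.1 CPM in WT and 3.81 ± 3.26 CPM in the labelled-null group (-2.58, 95% interval -4.13 to -1.03, adjusted p = 1.0). Cyp2b10 on ND was 4.88 ± 3.09 CPM in WT and 0.774 ± 0.225 CPM in the labelled-null group (-2.60, 95% interval -4.12 to -1.08, adjusted p = 0.186). On HFD it was 0.873 ± 0.510 CPM in WT and 1.06 ± 1.09 CPM in the labelled-null group (0.30, 95% interval -1.27 to 1.86). On ND the libraries of the male genotypes did not overlap for Cyp2b10, lower in the labelled-null group, or for Cyp2b9, higher there. No targeted gene passed between the male genotypes, so they do not settle the label, and the group is called males labelled Cyp2b-null throughout; every male direction between genotypes below is drawn from that label. Reads of these near-identical paralogues can be split or shared by the counting, so low counts at each of them are uncertain.

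**Figure D2:**
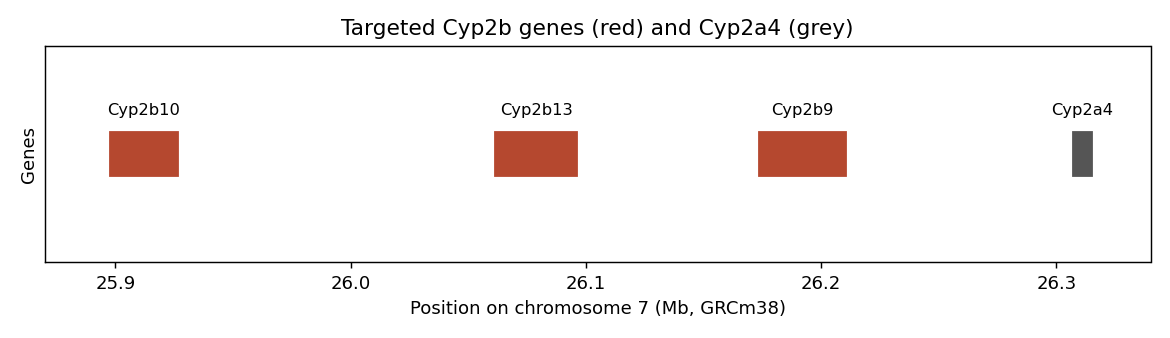
Map of the targeted genes (red) and Cyp2a4 (grey) on chromosome 7, with position in Mb of GRCm38 on the horizontal axis. Cyp2a4 begins 96.5 kb past the end of Cyp2b9.

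**Figure D3:**
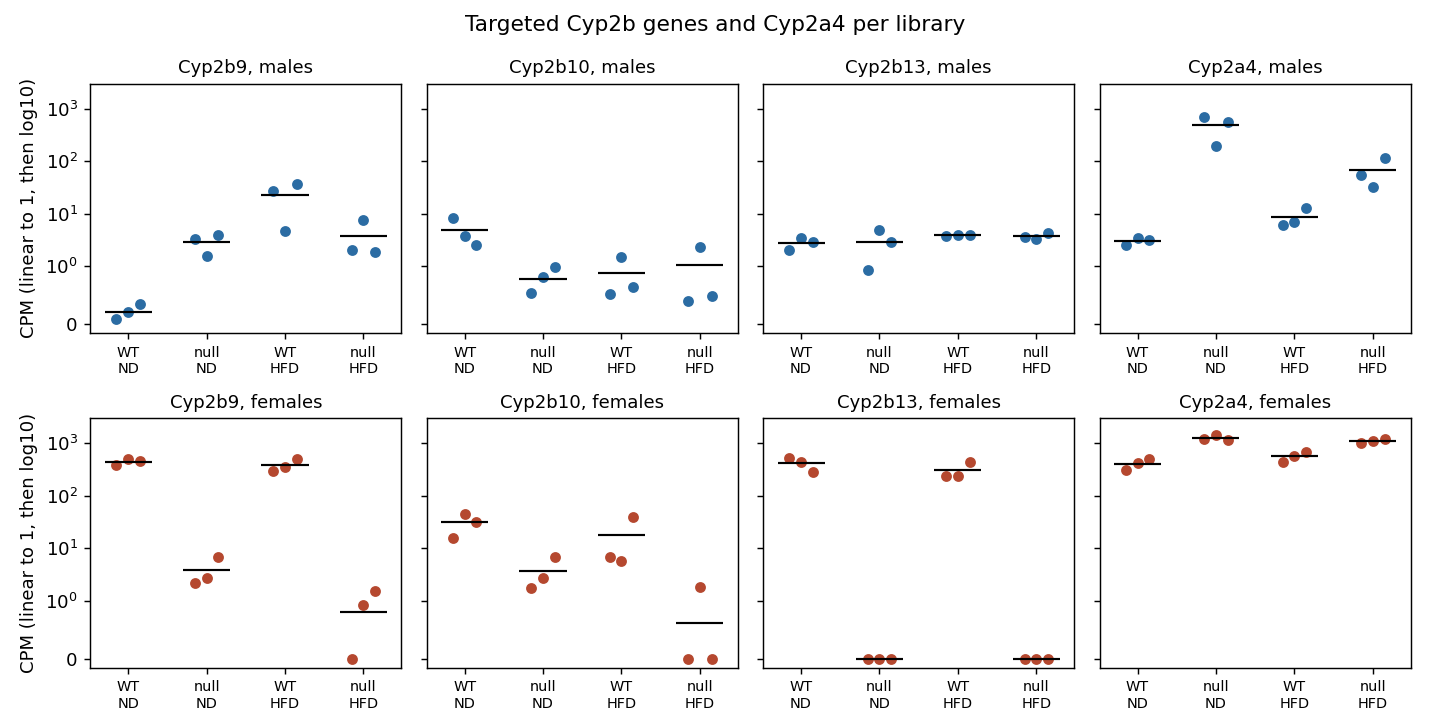
Points are the CPM of single libraries (vertical axis linear to 1 and log10 above) for Cyp2b9, Cyp2b10, Cyp2b13 and Cyp2a4 in the 4 groups of each sex, with a line at the group mean (n = 3). In females Cyp2b13 is at 0 in all 6 Cyp2b-null libraries, while in males it lies at the same low level in every group.

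On the normal diet, Dbp, Per3 and Cyp2a4 were among the genes higher in Cyp2b-null than in WT females. Dbp, a clock-controlled transcription factor, rose from 31.3 ± 11.9 to 204 ± 26.1 CPM (log2 2.71 ± 0.29, edgeR adjusted p = 0.000499). Per3, a period gene of the clock, rose from 2.19 ± 1.14 to 13.1 ± 3.73 CPM (2.58 ± 0.42, adjusted p = 0.0268), and Rgs16, a regulator of G-protein signalling, from 35.2 ± 12.4 to 569.8 ± 199 CPM (4.02 ± 0.58, adjusted p = 0.0268). Cyp2a4, a steroid hydroxylase whose gene begins 96.5 kb past the end of Cyp2b9, rose from 409.9 ± 96.9 to 1281 ± 171 CPM (1.64 ± 0.23, adjusted p = 0.00679). Prom1, which encodes a membrane glycoprotein used as a progenitor marker, fell from 14.8 ± 4.88 to 1.42 ± 0.170 CPM (-3.33 ± 0.46, adjusted p = 0.00679), and Tsc22d3, a glucocorticoid-induced leucine zipper protein, from 109 ± 24.5 to 38.8 ± 4.83 CPM (-1.48 ± 0.21, adjusted p = 0.00679). In all, 15 genes passed the test, 8 higher and 7 lower, against 749 at an unadjusted p under 0.05 and 76 called by DESeq2. Besides Cyp2b9 (-6.81 ± 0.45, adjusted p = 3.31e-06) and Cyp2b13 (adjusted p = 2.88e-05), Nrep, Arrdc3, Rassf4 and Nceh1 rose (2.07, 1.83, 1.81 and 1.53), and Dock6, Slc30a10, a manganese exporter, and Hexim1, an inhibitor of transcript elongation, fell (-1.60, -1.46 and -1.21). With the term for the female library sides 43 genes were called, 14 of the 15 among them. Dbp and Dock6 were also called between the diets in WT females, a comparison that uses the same WT ND libraries.

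Most of these calls were lost when 1 library was left out, which also lowers the power of the test. A call lost whichever library is left out does not rest on a single one. The Rassf4 difference, for instance, stayed between 1.76 and 1.93. Dbp, Cyp2a4, Cyp2b9 and Cyp2b13 passed whichever library was left out. Without WT ND library 1 the count was 7, without WT ND 3 it was 5, without Cyp2b-null ND 2 it was 8 and without Cyp2b-null ND 3 it was 5. Rassf4, Dock6 and Slc30a10 lost their call without any single one of the 6 libraries (adjusted p from 0.0777 to 0.174, 0.0584 to 0.257 and 0.0799 to 0.214). Hexim1 did so as well (0.0932 to 0.236). Nrep and Arrdc3 lost it without any library but Cyp2b-null ND 2 (0.079 to 0.151 and 0.0512 to 0.0784), and Nceh1 without any but WT ND 2 (0.079 to 0.161). When the compared groups alone were fitted Nceh1 and Hexim1 lost it too (0.0817 and 0.0823). Rgs16 lost it without WT ND 1, 2 or 3 (adjusted p = 0.188, 0.0893 and 0.161), without Cyp2b-null ND 2 or 3 (0.0785 and 0.079), and with the term for the library sides (0.107). Per3 lost it without WT ND 1 or 3 (0.118 and 0.151), without Cyp2b-null ND 1 or 3 (0.0777 and 0.0771), and when the compared groups alone were fitted (0.0656). Prom1 lost it without WT ND 3 (0.0784) or Cyp2b-null ND 3 (0.0504), and Tsc22d3 without Cyp2b-null ND 2 (0.0732).

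Gene lists fixed in advance were compared with the remaining genes by camera. In Cyp2b-null females on ND, targets of PPARα, the fatty-acid-sensing receptor, and genes of fatty acid oxidation were higher in 42 of 43 members (median 0.46, camera adjusted p = 1.06e-15). The call was lost at adjusted p = 0.365 with an estimated correlation. None of the 43 passed over all genes in edgeR, and 15 rose adjusted over the list alone. Among these 15, Fgf21, a hepatokine, was at 0.627 ± 0.322 CPM in WT and 8.33 ± 5.55 CPM in Cyp2b-null females (3.66 ± 0.86, adjusted p = 0.144). Clock genes were higher in 12 of 20 members (median 0.53, camera adjusted p = 2.53e-05), again with adjusted p = 0.365 with an estimated correlation. Over all genes Dbp and Per3 were called, and adjusted over the list alone 6 members were higher and 2 lower.

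Lipid synthesis genes were higher in Cyp2b-null females on ND as well. Cholesterol synthesis and uptake genes were higher in 23 of 25 (median 0.39, camera adjusted p = 0.000173), fatty acid and triglyceride synthesis genes in 22 of 27 (median 0.34, camera adjusted p = 0.00057) and lipid droplet genes in 16 of 22 (median 0.29, camera adjusted p = 0.0183). These calls were lost at adjusted p = 0.642, 0.365 and 0.365 with an estimated correlation. Adjusted over the list alone, 2, 2 and 3 of their members were higher and 1 lipid droplet gene was lower. Plin2, which coats lipid droplets, was at 238 ± 48.1 CPM in WT and 484 ± 108 CPM in Cyp2b-null females (1.02 ± 0.20, adjusted p = 0.0699; 0.0145 with the term for the library sides). Amino acid catabolism genes were lower in 28 of 31 (median -0.30, camera adjusted p = 0.00161) and mitochondrially encoded genes, which took the highest share in the WT ND 1 library, in 13 of 13 (median -0.51, camera adjusted p = 0.0268). With an estimated correlation the adjusted p was 0.642 and 0.777. Signs of handling and cell content moved as well. Immediate early genes were higher in 15 of 19 (median 1.19, camera adjusted p = 5.75e-05) and stellate cell and matrix genes in 18 of 22 (median 0.36, camera adjusted p = 0.0378), both with adjusted p = 0.642 with an estimated correlation. Camera called 12 lists here. Over the 85 other splits of the libraries within the female comparisons it called between 3 and 18 lists, with a median of 9. A count of called lists of this size thus also arises from other groupings of the libraries.

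On the high-fat diet, the genes that passed between female genotypes were targeted ones. Cyp2b9 fell (-8.82 ± 0.53, edgeR adjusted p = 9.48e-07) and so did Cyp2b13 (adjusted p = 4e-05; 0.289 with the term for the library sides). No other gene passed, against 289 at an unadjusted p under 0.05 and 2 called by DESeq2. Without WT HFD library 3, 4 genes passed. The other Cyp2 genes around the deleted cluster, tested without the targeted genes, were higher in 6 of 6 members (median 0.55, camera adjusted p = 1.74e-05). This list of 6 held with an estimated correlation (adjusted p = 0.0355), the single list call in the 10 comparisons within a sex that did so. With the term for the library sides it was lost (adjusted p = 0.185 with an estimated correlation). Cyp2a4 was the 1 member past the test adjusted over the list alone, at 567 ± 128 CPM in WT and 1113 ± 89.8 CPM in Cyp2b-null females (0.97 ± 0.22, adjusted p = 1.0 over all genes). Clock genes were higher in 14 of 20 (median 0.48, camera adjusted p = 5.67e-05), with Per3, Dbp and Usp2 higher adjusted over the list alone. The list had adjusted p = 0.384 with an estimated correlation. Female-biased genes were higher in 31 of 38 (median 0.25, camera adjusted p = 0.000243), and genes of the endoplasmic reticulum (ER) and integrated stress responses were lower in 25 of 27 (median -0.43, camera adjusted p = 6.94e-05). These had adjusted p = 0.0625 and 0.571 with an estimated correlation. Adjusted over the list alone Cyp2a4 and Acot3 of the female-biased genes were higher. Genes that make or metabolise polyunsaturated fatty acids, the substrates named in the series title, were higher in 32 of 42 by a small margin (median 0.12, camera adjusted p = 0.0394). That call was lost at adjusted p = 0.493 with an estimated correlation, and it was the only 1 of the 10 comparisons in which the list was called.

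In WT females Dbp was higher and Dock6 lower on HFD than on ND. Both genes were also called, in the same direction, in the female genotype comparison on ND. Both comparisons use the same WT ND libraries, so they are not independent. A shift of the WT ND group alone would give both results. Dbp rose from 31.3 ± 11.9 to 137 ± 42.0 CPM (2.14 ± 0.29, edgeR adjusted p = 0.0242) and Dock6 fell from 317 ± 43.2 to 85.1 ± 28.6 CPM (-1.90 ± 0.29, adjusted p = 0.0451). These were the 2 genes that passed, against 412 at an unadjusted p under 0.05, 23 called by DESeq2 and 15 with the term for the library sides. Among those 15, Cyp3a11, a drug-metabolising Cyp3a enzyme, fell from 2413 ± 358 to 1064 ± 155 CPM and Gstm3, a glutathione transferase, from 80.01 ± 13.7 to 26.8 ± 9.76 CPM. Fabp2, a fatty-acid-binding protein, rose from 61.4 ± 9.57 to 148 ± 16.3 CPM. The Dbp call was lost without WT ND 1 (adjusted p = 0.0512), WT ND 3 (0.275) or WT HFD 3 (0.16). The Dock6 call was lost without any WT library but WT HFD 1 (0.0512 to 0.393) or with RLE scaling (0.0533), and both were lost when the compared groups alone were fitted (0.312) or with the replicate number as a block (0.102), which left 0 genes. The count was 0 without WT ND 1, WT ND 3 or WT HFD 3, 1 without WT ND 2 or WT HFD 2, and 4 without WT HFD 1. PPARα targets and fatty acid oxidation genes were higher in 40 of 43 (median 0.36, camera adjusted p = 9.7e-13), with 0 called adjusted over the list alone and adjusted p = 0.449 with an estimated correlation. Targets of the xenobiotic receptors CAR and PXR were lower in 27 of 33 (median -0.24, camera adjusted p = 2.23e-07), 4 of them adjusted over the list alone (Gstm3, Cyp3a11, Cyp3a25 and Aldh1a7). The adjusted p of that list was 0.221 with an estimated correlation. Interferon response genes were higher in 24 of 29 (median 0.44, camera adjusted p = 7.98e-06), as were markers of Kupffer cells, the resident macrophages, in 21 of 22 (median 0.36, camera adjusted p = 3.2e-05). With an estimated correlation they had adjusted p = 0.481 and 0.49. Camera called 13 lists here and 13 in the female genotype comparison on HFD.

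In Cyp2b-null females the diet effect passed for 0 genes in edgeR, against 568 at an unadjusted p under 0.05 and 3 called by DESeq2. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids (chromosome 19, 44394455 to 44407879, GRCm38), stood at 6625 ± 1865 CPM on ND and 2424 ± 278 CPM on HFD (-1.45 ± 0.22, adjusted p = 0.0757), and was the 1 gene called with the term for the library sides (adjusted p = 0.000314). Interferon response genes were higher on HFD in 26 of 29 members (median 0.66, camera adjusted p = 3.81e-12), with 8 higher adjusted over the list alone and adjusted p = 0.397 with an estimated correlation. Gbp7, a guanylate-binding protein, was at 16.8 ± 2.10 and 47.9 ± 21.6 CPM. Kupffer cell markers were higher in 22 of 22 (median 0.77, camera adjusted p = 4.4e-11), with adjusted p = 0.399 with an estimated correlation. Fcer1g, an Fc receptor chain, was at 7.80 ± 2.24 and 15.8 ± 4.95 CPM. Cholesterol synthesis genes were lower in 23 of 25 (median -0.64, camera adjusted p = 4.69e-10), and fatty acid and triglyceride synthesis genes in 17 of 27 (median -0.28, camera adjusted p = 0.00012). With an estimated correlation the adjusted p was 0.399 and 0.397. In the second of these lists Me1, Lpin2 and Scd1 were lower adjusted over the list alone. Immediate early genes, which respond to handling, were lower in 18 of 19 (median -0.81, camera adjusted p = 0.000125), with adjusted p = 0.591 with an estimated correlation. Camera called 9 lists.

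The interaction in females, the diet effect in Cyp2b-null minus that in WT, passed for 0 genes in edgeR, against 342 at an unadjusted p under 0.05 and 11 called by DESeq2. Without WT HFD library 1, 1 gene passed. The smallest p over the fixed lists belonged to Prom1 (3.90 ± 0.66, adjusted p = 0.344), and Scd1 had -1.39 ± 0.30 (adjusted p = 0.407). With the term for the library sides 2 genes were called, Scd1 (-1.44) and Arrdc3 (-2.03), both at an adjusted p of 0.0352. Camera called 10 lists, among them PPARα targets and fatty acid oxidation, lower in 34 of 43 (median -0.31, camera adjusted p = 0.00023), and fatty acid and triglyceride synthesis, lower in 20 of 27 (median -0.37, camera adjusted p = 0.00107). These had adjusted p = 0.752 and 0.656 with an estimated correlation.

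On the normal diet, males labelled Cyp2b-null carried far more Cyp2a4 than WT males. It rose from 3.02 ± 0.481 to 485 ± 259 CPM (7.33 ± 0.68, 95% interval 5.84 to 8.81, edgeR adjusted p = 0.00226; 0.151 when the compared groups alone were fitted). Ifit1bl1, an interferon-induced gene, rose from 1.10 ± 0.598 to 9.86 ± 1.67 CPM (3.13 ± 0.40, adjusted p = 0.0364). That call was lost without WT ND 2 (0.214), WT ND 3 (0.175) or labelled-null ND 3 (0.162) and when the compared groups alone were fitted (0.502). These were the 2 genes that passed, against 2759 at an unadjusted p under 0.05 and 427 called by DESeq2, 300 higher and 127 lower. The count was 1 without WT ND 2 or labelled-null ND 3, 724 without labelled-null ND 2, and 7 without the divergent library, labelled-null ND 1. Among the 7, Wee1, a cell-cycle kinase under clock control, rose (2.73, adjusted p = 0.00783), as did Gys2, the liver glycogen synthase (1.45, adjusted p = 0.0496), Map2k6 and Fbf1. Slc45a3 fell (-1.31).

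Among the fixed lists, genes of the endoplasmic reticulum (ER) and integrated stress responses were lower in 20 of 28 members in males labelled Cyp2b-null on ND (median -0.98, camera adjusted p = 1.37e-07). Adjusted over the list alone 14 were lower and 1 higher, and the list had adjusted p = 0.295 with an estimated correlation. Fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, gave this list an adjusted p of 0.0329. Manf, a secreted ER protein, was at 209.9 ± 64.5 CPM in WT and 38.5 ± 9.27 CPM in the labelled-null group (-2.44 ± 0.45, adjusted p = 0.165). Clock genes were higher in 17 of 21 (median 0.85, camera adjusted p = 9.41e-06; fry adjusted p = 0.012), with 13 higher and 2 lower adjusted over the list alone. The camera call was lost at adjusted p = 0.172 with an estimated correlation. Arntl, which encodes the activator BMAL1, was at 11.9 ± 6.61 and 2.14 ± 0.495 CPM (-2.49 ± 0.47, adjusted p = 0.165). Cholesterol synthesis genes were lower in 23 of 25 (median -0.72, camera adjusted p = 2.48e-05), with Mvk, mevalonate kinase, at 30.2 ± 7.81 and 16.8 ± 4.79 CPM and adjusted p = 0.602 with an estimated correlation for the list. Male-biased genes were lower in 26 of 32 (median -0.56, camera adjusted p = 0.000273), again at 0.602 for the adjusted p with an estimated correlation. Elovl3, a fatty acid elongase, was at 391 ± 171 and 45.4 ± 24.7 CPM (-3.10 ± 0.53, adjusted p = 0.122). Camera called 17 lists. Hepatocyte markers were among them, lower in 14 of 16 (median -0.67, camera adjusted p = 0.000102; 0.00109 without the divergent library), with adjusted p = 0.602 with an estimated correlation. Several lists moved with the divergent library. Mitochondrially encoded genes were higher in 13 of 13 (median 1.44, camera adjusted p = 0.00114; 0.739 without that library), with adjusted p = 0.602 with an estimated correlation. Lymphocyte markers were higher in 15 of 15 (median 1.37, camera adjusted p = 0.00198; 0.714 without it) and adipocyte markers in 6 of 7 (median 1.21, camera adjusted p = 0.0483; 0.714 without it). Both also had adjusted p = 0.602 with an estimated correlation. The male-biased genes had a camera adjusted p of 0.145 without that library. The ER, clock and cholesterol lists stayed called without it (camera adjusted p = 3.67e-09, 1.46e-07 and 0.00428), with adjusted p = 0.51, 0.211 and 0.927 with an estimated correlation.

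On the high-fat diet 0 genes passed between the male genotypes in edgeR, against 315 at an unadjusted p under 0.05 and 18 called by DESeq2. Fitting the compared groups alone called 3. Cyp2a4 stood at 8.62 ± 3.69 CPM in WT and 67.3 ± 42.9 CPM in males labelled Cyp2b-null (2.95 ± 0.55, 95% interval 1.75 to 4.16, adjusted p = 0.511). Cry1, a repressor of the clock, was at 7.02 ± 1.88 and 20.7 ± 4.77 CPM (1.56 ± 0.28, adjusted p = 0.367). Cholesterol synthesis genes were lower in 24 of 25 members (median -0.58, camera adjusted p = 5.02e-11), with Fdps, farnesyl diphosphate synthase, at 203 ± 109 and 85.7 ± 29.6 CPM. The list had adjusted p = 0.537 with an estimated correlation. ER and integrated stress response genes were lower in 25 of 28 (median -0.39, camera adjusted p = 1.47e-07), with adjusted p = 0.286 with an estimated correlation. Of these, Chac1, a glutathione-degrading enzyme, was the 1 adjusted over the list alone (4.44 ± 1.96 and 0.981 ± 0.394 CPM). Cell cycle genes were higher in 15 of 18 (median 0.27, camera adjusted p = 3.73e-05), with adjusted p = 0.234 with an estimated correlation. Camera called 7 lists, and 13 without WT HFD library 2.

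High-fat feeding of WT males passed for 0 genes in edgeR, against 966 at an unadjusted p under 0.05 and 85 called by DESeq2. Without the divergent library, which belongs to neither compared group but enters the shared estimate of spread, 109 passed, 66 higher and 43 lower. In the simulation with 11 male libraries, of the genotype comparison on ND, false calls were over 0.05 of all calls. Fitting the compared groups alone called 21. Among the 109, Vnn1, a pantetheinase under PPARα control, rose from 38.2 ± 12.7 to 136 ± 24.6 CPM (1.84, adjusted p = 0.00606), and Ppara itself from 235 ± 12.4 to 523 ± 63.3 CPM (1.15, adjusted p = 0.015). Themis, a gene of T-cell selection, rose from 0.432 ± 0.347 to 4.05 ± 0.221 CPM (3.20, adjusted p = 0.0236). Csad, which makes hypotaurine on the way to taurine, fell from 589 ± 125 to 111 ± 3.55 CPM (-2.40, adjusted p = 0.000152), and Cyp3a41a, a female-biased Cyp3a enzyme, from 135 ± 20.2 to 23.8 ± 8.63 CPM (-2.51, adjusted p = 0.00314). Cyp2b9, at 0.215 ± 0.128 CPM on ND and 22.5 ± 16.1 CPM on HFD, was also among them (6.66, adjusted p = 0.0381). With all 12 libraries its difference was 6.65 (95% interval 4.53 to 8.77, adjusted p = 0.0876). In the fit of all 12, PPARα targets and fatty acid oxidation genes were higher in 39 of 44 (median 0.48, camera adjusted p = 2.36e-10), Vnn1 and Ppara adjusted over the list alone, with adjusted p = 0.441 with an estimated correlation for the list. Antioxidant genes under NRF2 were lower in 21 of 26 (median -0.34, camera adjusted p = 8.03e-08), with Gstm3, Gstm1, Gsta1 and Gsta2 adjusted over the list alone. That list had an adjusted p of 0.318 with an estimated correlation. Gstm3 was at 69.8 ± 23.3 and 14.4 ± 6.80 CPM. Clock genes were higher in 16 of 21 (median 0.78, camera adjusted p = 1.4e-07), 4 higher and 1 lower adjusted over the list alone, and ribosomal protein genes were lower in 44 of 47 (median -0.51, camera adjusted p = 1.57e-12). They had adjusted p = 0.126 and 0.318 with an estimated correlation. Signs of cell content and tissue handling moved too. Immediate early genes were lower in 17 of 20 (median -0.61, camera adjusted p = 0.000409) and hepatocyte markers in 14 of 16 (median -0.33, camera adjusted p = 0.0184), while adipocyte markers were higher in 6 of 7 (median 0.39, camera adjusted p = 0.00874) and mitochondrially encoded genes in 12 of 13 (median 0.46, camera adjusted p = 0.0202). These 4 lists had adjusted p = 0.494, 0.585, 0.441 and 0.698 with an estimated correlation. Camera called 18 lists.

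In males labelled Cyp2b-null the diet effect also passed for 0 genes in edgeR, against 1657 at an unadjusted p under 0.05 and 117 called by DESeq2. Without the divergent library, labelled-null ND 1, 13 passed, and without labelled-null ND 2, 28 passed. Among the 13, Ppp1r3b, which targets phosphatase 1 to glycogen, rose from 108 ± 49.98 to 553 ± 69.9 CPM (2.08, adjusted p = 0.0178), and Csad fell from 368 ± 168 to 58.8 ± 9.69 CPM (-2.97, adjusted p = 2.77e-05). The ND means and SDs here include the divergent library, while the log2 differences and adjusted p leave it out. PPARα targets and fatty acid oxidation genes were higher in 37 of 44 (median 0.47, camera adjusted p = 5.74e-07) and markers of pericentral hepatocytes in 19 of 19 (median 0.50, camera adjusted p = 0.000511), both with adjusted p = 0.881 with an estimated correlation. Both lists were low in the divergent library, and without it their medians were 0.22 (38 of 44 higher, camera adjusted p = 3.43e-05) and 0.17 (16 of 19 higher, camera adjusted p = 0.0072). The adjusted p was then 0.837 for each with an estimated correlation. Lymphocyte markers, high in the divergent library, were lower in 13 of 15 (median -0.90, camera adjusted p = 0.0457; 0.505 without that library), with adjusted p = 0.881 with an estimated correlation. Camera called 6 lists.

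The male interaction passed for 0 genes in edgeR, against 691 at an unadjusted p under 0.05 and 18 called by DESeq2. Without the divergent library, labelled-null ND 1, Slc45a3 alone passed (2.29, adjusted p = 0.00764). Camera called 13 lists for it, among them clock genes, lower in 15 of 21 (median -0.63, camera adjusted p = 0.00219). That list had adjusted p = 0.649 with an estimated correlation, and a camera adjusted p of 0.00214 without the divergent library. Lists that stood out in that library were called too. Mitochondrially encoded genes were lower in 13 of 13 (median -1.39, camera adjusted p = 0.00181; 0.73 without it), lymphocyte markers in 12 of 15 (median -1.31, 0.0118; 0.73 without it) and adipocyte markers in 6 of 7 (median -1.25, 0.0375; 0.603 without it), and hepatocyte markers were higher in 14 of 16 (median 0.44, 0.00666; 0.157 without it). These had adjusted p = 0.649, 0.653, 0.649 and 0.649 with an estimated correlation. Over the 85 other splits of the libraries within the male comparisons it called between 1 and 20 lists, with a median of 12.

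**Figure D4:**
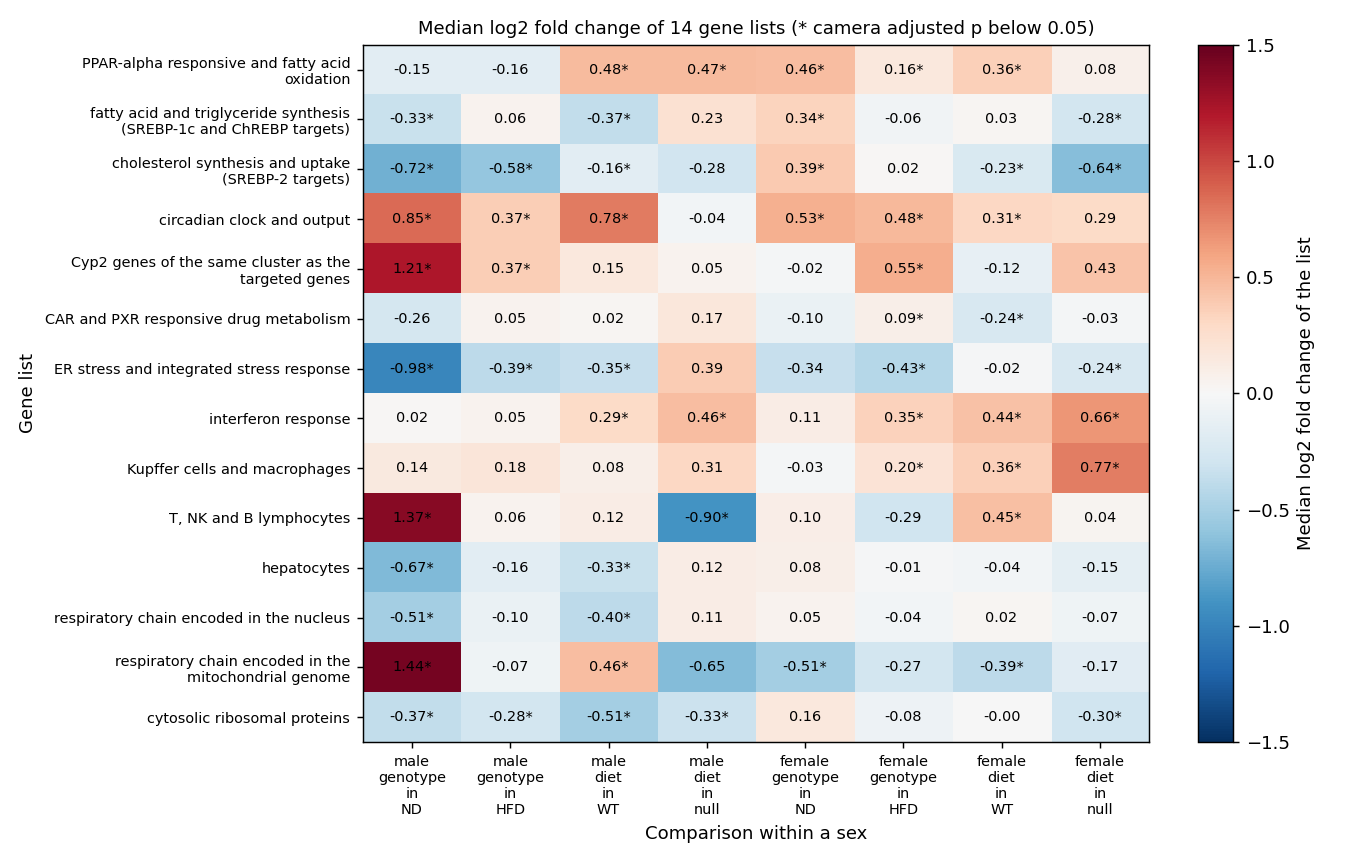
Each cell gives the median log2 difference of a gene list (vertical axis) in a comparison within a sex (horizontal axis), coloured from blue (lower) to red (higher), with a star where the camera adjusted p with its preset correlation lay below 0.05. With an estimated correlation the call held in 1 cell, the Cyp2 genes of the cluster in the female genotype comparison on HFD.

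**Figure D5:**
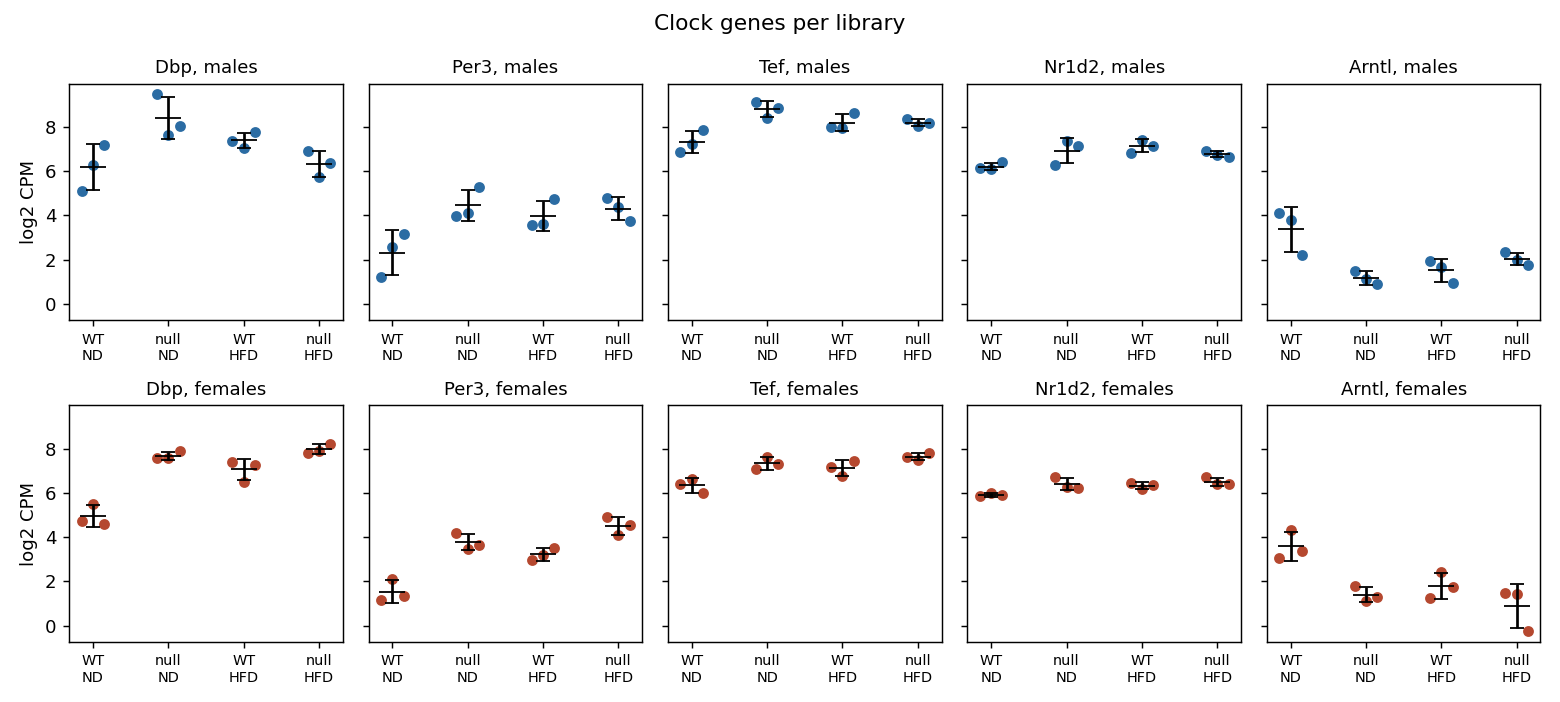
Points are the log2 CPM of single libraries for the clock genes Dbp, Per3, Tef, Nr1d2 and Arntl in the 4 groups of each sex, with the group mean ± SD (n = 3). In females every WT ND library lies below every other library for Dbp, Per3 and Tef and above every other library for Arntl; the male groups overlap more.

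The genotype effect was compared between the sexes in a joint fit of the 24 libraries over 15043 genes, as the female effect minus the male effect. On ND 5 genes differed, all lower in females by this measure, against 1760 at an unadjusted p under 0.05 and 42 called by DESeq2. They were the targeted Cyp2b9 and Cyp2b13, Cyp2a4 (-5.68 ± 0.63, edgeR adjusted p = 3.17e-05), Prom1 (-4.32 ± 0.70, adjusted p = 0.00991) and the predicted gene Gm15343 (-2.60 ± 0.43, adjusted p = 0.0135), named here after its values were seen. Cyp2a4 rose in both sexes, and from a lower WT level in males. Prom1 and Gm15343 lost their call without male WT ND 2 or female Cyp2b-null ND 2 or 3, Gm15343 also without male WT ND 3 or female WT ND 1, and both when the compared groups alone were fitted (0.346 and 0.0785). The count was 12 without male WT ND 1, 219 without male labelled-null ND 2, 10 without female WT ND 3, and 3 without male WT ND 2 or female Cyp2b-null ND 2 or 3. On HFD Cyp2b9 and Cyp2b13 differed, against 231 genes at an unadjusted p under 0.05 and 2 called by DESeq2. Cyp2b9 (-6.32 ± 1.03, adjusted p = 0.0264) kept its difference without the divergent male library (-6.30) but lost its call (0.299), as it did when the compared groups alone were fitted (1.0). The count was 1 without male WT HFD 1, male labelled-null HFD 2, female WT HFD 2 or 3, or any 1 female Cyp2b-null HFD library. The diet effect in WT differed between the sexes for Cyp2b9 alone (-6.80 ± 0.98, adjusted p = 0.00834; -6.80 with an adjusted p of 0.109 without the divergent male library, and 0.335 when the compared groups alone were fitted), against 558 genes at an unadjusted p under 0.05 and 1 called by DESeq2. It differed for 0 genes without male WT ND 1, 2 or 3 or female WT HFD 1 or 2. The diet effect in the null groups differed for 0 genes in edgeR, against 699 at an unadjusted p under 0.05 and 0 called by DESeq2. In edgeR 1 gene differed without male labelled-null ND 2.

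Few calls were shared between comparisons. The female genotype comparisons on ND and HFD shared Cyp2b9 and Cyp2b13 (2 genes, 0.00118 for independent lists), and the male and female genotype comparisons on ND shared Cyp2a4 (1 gene, 0.00144 for independent lists); the other pairs examined shared 0 in these fits. By DESeq2 the diet effects in WT males and in males labelled Cyp2b-null shared 10 genes, all in the same direction (0.341 for independent lists). In edgeR without the divergent male library these diet effects shared 5 (0.046 for independent lists): Cyp3a41a, Cyp3a44, Tuba8, Themis and Csad. By DESeq2 the male and female genotype comparisons on ND shared 14 genes in the same direction and 2 in the opposite one (1.19 for independent lists), among them Dbp, Per3, Tef, Wee1 and Arntl of the clock and Gys2 and Ppp1r3b of glycogen metabolism. These come from separate libraries in each sex. In edgeR, without the divergent male library and with the term for the female sides, the diet effects in WT males and females shared 4 genes (0.0625 for independent lists): Nceh1, Fabp2, Cyp3a11 and Chka.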

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

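The tests below of where the male Cyp2b reads come from, and the tally of splits that keep a real grouping, were chosen only after the result was seen; the differences between the sexes and the splits of the libraries were set in advance.

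The results below stood out because the same contrast gave different effects in females and males when the difference itself was tested, as the female minus the male log2 effect in the joint edgeR fit. For the genotype effect on ND the difference was -14.91 for Cyp2b13, -10.44 for Cyp2b9, -5.68 for Cyp2a4, -4.32 for Prom1 and -2.60 for Gm15343. On ND Cyp2b13 was at 2.72 CPM in WT males and 421 CPM in WT females, and Cyp2b9 at 0.215 and 450 CPM. WT males thus had little of either transcript to lose. Prom1 had -3.33 in females and 0.96 in males (adjusted p = 0.31 in males), and Gm15343 -1.77 and 0.82, neither called within a sex. For the genotype effect on HFD it was -14.29 for Cyp2b13 and -6.32 for Cyp2b9, and for the diet effect in WT -6.80 for Cyp2b9. The values for Cyp2b13 depend on the prior count, since all 6 female Cyp2b-null libraries hold 0 counts, and are no bound. Sex goes with the RNA extraction and the library kit, so these differences cannot be told apart from a difference between kits.

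Among 50 drawn splits of the libraries, the real one included, 2 gave as many genes as the 5 of the sex difference of genotype on ND (highest other 9). These splits exchange genotype labels within both sexes, so they ask whether genotype had any effect. The loss of Cyp2b9 and Cyp2b13 in females already answers that. The splits therefore cannot exclude chance for a difference between the sexes, nor for Prom1 or Gm15343. The split with 9 genes put the real female groups the other way round, so it carries the female genotype effect, and the 41 splits mixed in both sexes gave at most 1. For genotype on HFD 6 of 50 gave as many as 2 (highest other 19), so the splits do not exclude chance for that count. Of the others as large, 2 kept a real grouping and 3 were mixed in both sexes. The 2 genes were the targeted Cyp2b9 and Cyp2b13. On HFD Cyp2b13 had 565 to 1096 counts in WT females and 0 in the Cyp2b-null ones. These counts argue against chance for its loss in females. For diet in WT 7 of 50 gave as many as 1 (highest other 1), but 5 of the others kept the real grouping of one sex and with it the diet effect there, so these splits leave chance undecided. For diet in the null groups all 50 gave at least the 0 of the real split (highest other 6). The split with 19 genes was mixed in both sexes, and its female groups do not follow the sides of the first principal component. Whether it reflects another structure of the samples or a single extreme draw was not tested.

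Cyp2b9 and Cyp2b13 reads occurred in males labelled Cyp2b-null. That these males are wild type is argued against by Cyp2b9 on HFD, whose 95% interval ended at -1.03, below 0, though this interval is unadjusted, rests on 3 against 3 libraries that overlap (WT from 4.67 CPM, labelled-null up to 7.57 CPM), and the difference had the opposite sign on ND. Cyp2b10 on ND also ran the way of the label, at -2.60 with an unadjusted 95% interval of -4.12 to -1.08 and no overlap of libraries. On HFD Cyp2b10 did not, at 0.30 with an unadjusted 95% interval of -1.27 to 1.86. Reads of Cyp2b9 or Cyp2a4 counted at Cyp2b13 at constant rates are argued against as the whole source on HFD: the highest rates that the male libraries other than the divergent one allow (13.2% of Cyp2b9 and 0.666% of Cyp2a4 counts) give at most 24.2% of the 146 Cyp2b13 counts of the labelled-null group. On ND they give up to 94.4% of its 139 counts, but these counts include the divergent library, which was left out when the rates were set. That library had 7 Cyp2b13 counts at 5177 Cyp2a4 counts, a lower rate than the one applied, so 94.4% is too high if it counts. Whether this source could be the whole on ND is thus not settled, and as a part it stays open on both diets. Across the male libraries Cyp2b13 ranged 5.11-fold while Cyp2b9 ranged 417-fold and Cyp2a4 276-fold. The lowest Cyp2b13 level, 0.937 CPM, was that of the divergent library, and the other male libraries ran from 1.99 to 4.78 CPM. Cyp2b-null females had 0 Cyp2b13 counts at 1281 and 1113 CPM of Cyp2a4, in libraries of another kit. Over the 12 male libraries Cyp2b13 had a Spearman rho of 0.217 with Cyp2b9 and 0.0839 with Cyp2a4 (permutation p = 0.502 and 0.802, both 0.802 adjusted over the pair). The Pearson r was 0.234 and -0.53 (permutation p = 0.452 and 0.0708, 0.452 and 0.142 adjusted). Without the 2 farthest libraries r was 0.0335 and 0.709. A residual transcript of the edited locus is a candidate explanation that also stays open: Cyp2b9 and Cyp2b10 had a Pearson r of 0.932 over the 6 labelled-null male libraries (exact permutation p = 0.0292; Spearman rho 0.6, exact permutation p = 0.242), but -0.32 without the 2 farthest libraries, so the relation rests on those. The first criterion of that test was met, the demand that r hold without 2 libraries was added after its value was seen, and a difference in the deletion between the sexes was not tested.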

How the results depend on the processing

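The term for the female library sides and the fits without the divergent male library were chosen after the data were seen; the other alternatives were listed in advance. Depth limits mainly the female libraries, and without the filter on low counts more genes were tested and called: 35, 6 and 26 for male genotype on ND, diet in WT and diet in null, 121, 12, 38, 30 and 23 for female genotype on ND and HFD, diet in WT, diet in null and interaction, and 215, 12, 33 and 84 for the sex differences of genotype on ND and HFD and of diet in WT and null. DESeq2 called 427, 18, 85, 117 and 18 genes in the male comparisons in the order genotype on ND and HFD, diet in WT and null and interaction, 76, 23, 3 and 11 in females for genotype on ND, diet in WT and null and interaction, and 42 for the sex difference of genotype on ND. Fitting the compared groups alone called 0, 3 and 21 genes for male genotype on ND and HFD and diet in WT, 0 for female diet in WT, and 3, 1 and 0 for the sex differences of genotype on ND and HFD and diet in WT. Without the divergent male library the counts were 7 for genotype on ND, 109 and 13 for diet in WT and null, 1 for the interaction, and 1 and 0 for the sex differences of genotype on HFD and diet in WT. With the term for the female library sides they were 43, 1, 15, 1 and 2. RLE scaling left 1 gene for female diet in WT. For the other settings that moved a count the cause was not tested.

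With the replicate number as a block over all groups of a fit, female diet in WT went from 2 genes to 0, with a log2 difference of 2.12 for Dbp and -1.95 for Dock6. There the numbers were taken to pair the libraries. This block, however, gives each number the same effect in all groups of the fit. Same-numbered female libraries of the genotype comparison on ND deviated in opposite ways (r from -0.374 to -0.167). The loss therefore cannot decide whether the 2 calls hold under a pairing within WT alone, which was not fitted. Male diet in WT stayed at 0. In the other comparisons within a sex the libraries share only a number: over all groups 10 of 18 same-numbered pairs in males and 6 of 18 in females deviated together with r above 0.1, and 5 and 6 of 12 libraries correlated best with their own number. There the block gave 1 gene for male genotype on ND and 8 for female genotype on ND, and it gave 1 for the sex difference of genotype on HFD. The block moved no other count of genes or lists by over 1.5 times.

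With an estimated correlation camera called 0 lists in every comparison within a sex but female genotype on HFD, where it called 1. Leaving out each library of the compared groups in turn gave between 1 and 724 genes for male genotype on ND, 0 and 1 for diet in WT, 0 and 28 for diet in null and 0 and 1 for the interaction. In females it gave 5 to 12 for genotype on ND, 2 to 4 on HFD, 0 to 4 for diet in WT and 0 to 1 for the interaction, and for the sex differences 3 to 219, 1 to 2, 0 to 1 and 0 to 1. The counts for male genotype on HFD and female diet in null stayed at 0 in edgeR (315 and 568 at an unadjusted p under 0.05). Lists called ranged from 13 to 18, 8 to 13, 13 to 18, 7 to 9 and 11 to 16 in the male comparisons and from 8 to 13, 9 to 14, 8 to 13, 9 to 14 and 5 to 13 in the female ones, in the order above.

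Of the values of named genes under the alternatives, 3120 kept direction and side of the threshold, 225 passed it only under the alternative, 85 no longer passed it and 24 changed sign. Changes of sign without the divergent library gave -0.0304 for Cyp2b13, male diet in null, 1.83 for Acta2, male diet in null, 0.52 for Ndufa5, male interaction, and 1.96 for Acta2, male interaction. Over the single libraries left out, the log2 values that changed sign ranged from -0.49 to 0.49 for Cyp2b13, male genotype in ND, from -0.95 to 0.82 for Cyp2b10, male genotype in HFD, and from -0.15 to 0.0529 for Cyp2b13, male genotype in HFD. They ranged from -0.55 to 0.74 for Cyp2b9, male diet in null, from -0.86 to 0.81 for Cyp2b10, male diet in null, from -0.0304 to 0.93 for Cyp2b13, male diet in null, and from -0.53 to 0.46 for Cyp2b13, male interaction. For list members they ranged from -1.46 to 0.20 for Tagln, male genotype in ND, from -1.05 to 0.0336 for Gsta1, male genotype in ND, from -2.90 to 1.83 for Acta2, male diet in null, from -2.75 to 1.96 for Acta2, male interaction, and from -0.45 to 0.52 for Ndufa5, male interaction. In females they ranged from -0.0543 to 1.16 for Gbp3, female genotype in HFD, from -0.81 to 0.0724 for COX2, female genotype in ND, from -0.71 to 0.16 for COX2, female genotype in HFD, and from -0.18 to 0.72 for ND2, female interaction. None of these passed the threshold in the fit reported, and the cause was not tested.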

Other observations

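The tests of the clock genes, of the called lists over splits, of splits that keep a real grouping or part numbered pairs, and of GC content as the whole of the difference of the divergent library were chosen only after the results were seen; the splits of gene counts and the other tests of that library were written before.

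Some gene lists changed in comparisons where the report did not describe them. Stellate cell and matrix genes were lower in Cyp2b-null than in WT females on HFD in 18 of 22 (median -0.35, camera adjusted p = 0.000659; adjusted p = 0.571 with an estimated correlation), and lower in 18 of 22 in the interaction (median -0.57, camera adjusted p = 5.31e-05; adjusted p = 0.656 with an estimated correlation). Ribosomal protein genes were lower in males labelled Cyp2b-null in 35 of 47 on ND (median -0.37, camera adjusted p = 2.48e-05; adjusted p = 0.602 with an estimated correlation) and in 46 of 47 on HFD (median -0.28, camera adjusted p = 6.06e-07; adjusted p = 0.608 with an estimated correlation). Nuclear genes of the respiratory chain were lower in 39 of 44 in males labelled Cyp2b-null on ND (median -0.51, camera adjusted p = 1.37e-07; adjusted p = 0.602 with an estimated correlation) and in 40 of 44 in WT males on HFD (median -0.40, camera adjusted p = 9.85e-07; adjusted p = 0.455 with an estimated correlation). Bile acid genes were called in 0 of the 10 comparisons by camera.

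The divergent male library, labelled-null ND 1, deviated by over 1 (log2) from the mean of the other 11 male libraries in 7423 of 14873 genes. Loss of long transcripts is argued against by the Spearman rho of the deviation with transcript length across genes, -0.00116 (-0.317 to 0.356 in the other libraries). GC content may account for part of it, with a rho of 0.415. The other libraries ran from -0.502 to 0.359, so another library had a larger absolute value. Of 13640 genes with a GC value, 6776 lay over 1 from the median deviation before that trend was removed. After its removal 6070 genes did, 89.6% as many, though not necessarily the same genes. GC content is thus not the whole. Cells of another type stay open: among the lists of other cell types lymphocyte markers had the highest median deviation, 1.91, between the bounds set beforehand, with Igkc at 68.6 against 3.34 CPM, adipocyte markers had 1.31 (5 of 7 above 1), stellate markers 0.95 (13 of 26 above 1) and hepatocyte markers -1.34 (10 of 16 below -1), but Kupffer markers had -0.58. Immediate early genes, which respond to handling, were also high in that library (median deviation 1.43, 14 of 20 above 1). Genes are not independent replicates, and the library was kept in the fits as designed.

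Clock genes of the WT ND group differed from the mean of the other 3 groups of the same sex, though in males not from each group for every gene: Dbp was at 5.11 to 7.16 log2 CPM in WT ND and 5.73 to 6.90 in labelled-null HFD males. Evening genes minus morning genes, WT ND minus the mean of the other groups, had a median difference of -1.78 in males and -2.14 in females, with 6 of 7 evening genes lower in males (Nr1d1 was the exception, at 0.94), 7 of 7 in females, and 3 of 3 morning genes higher in both. This is consistent with a different clock phase in the WT ND livers at sampling. The divergent male library as its cause is argued against by the male evening median of -1.04 without it (-1.19 with it; -1.20 in females). Whether the phase differed because of the time of sampling or because genotype and diet shift the clock stays open, since the labels used here give no time.

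The 3 against 3 comparisons allow 10 splits, too few for a share under 0.05. The real count of genes was reached by 1 split (the real one) on ND between genotypes in males (2 genes, highest other 0) and females (15, highest other 2), and between genotypes on HFD (2, highest other 0) and diets in WT (2, highest other 0) in females; by all 10 in the male genotype comparison on HFD, the male diet comparison in WT and that in the labelled-null group (0, highest other 0) and in the diet comparison of Cyp2b-null females (0, highest other 8). The split with 8 genes put Cyp2b-null ND 1, HFD 1 and HFD 3 against the rest, which is how the first principal component parts these libraries; with a term for its sides 1 gene was called. In the fits added later the real count was reached by 1 split each: 109 genes for diet in WT males without the divergent library (highest other 0), 43 for genotype on ND in females (highest other 3) and 15 for diet in WT females (highest other 2), both with the term for the library sides. The fits added later did not use the replicate numbers that were taken to pair the WT libraries. For the interactions all 50 drawn splits gave at least 0 genes, with up to 21 in males and 11 in females. Both of these splits kept the real ND grouping, and the one in females turned the real HFD grouping round, which adds up the genotype effects of both diets. The 41 splits mixed on both diets gave at most 0 genes in males and 2 in females. Among the 4 splits that part every same-numbered pair of WT libraries, the real one had 2 genes in females (highest other 0) and 0 in males (highest other 0).

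Counts of lists called by camera were reached or passed by other splits in every comparison within a sex but the male genotype comparison on ND. The real count was reached by 1 of 10 splits for genotype on ND in males (17, highest other 15), by 2 of 10 for diet in WT males (18, highest other 20), genotype on ND in females (12, highest other 18), genotype on HFD in females (13, highest other 14) and diet in WT females (13, highest other 15), by 8 of 10 for diet in Cyp2b-null females (9, highest other 15) and by 10 of 10 for genotype on HFD in males (7, highest other 18) and diet in the labelled-null males (6, highest other 16). For the interactions 27 of 50 in males (13, highest other 19) and 25 of 50 in females (10, highest other 16) reached it, so chance cannot be excluded there. The 10 splits of a 3 against 3 comparison are too few for a share under 0.05.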
